A study of Mus musculus with 12 samples.

How the data were processed

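The data are RNA-seq read counts per gene from liver sections of 12 mice, 4 each of lean, HFD control and NM-FGF19. Per the labels, libraries were made from 100 ng of total RNA with a stranded Illumina mRNA kit and sequenced on a NextSeq2000 as read pairs of 101 nt. The deposited table holds raw counts for 55359 genes, made by the authors with Trimmomatic, STAR and featureCounts on the mouse build mm39, per the submitters' processing notes. Tool versions, the gene annotation and the strand mode of counting are not given in the sources used here, so overlapping genes on opposite strands may share reads. All values were whole numbers, and all 12 columns were mapped to samples by the names in the labels, with 0 columns left over. The HFD control columns carry the name mOX40L, which stands for the mouse gene Tnfsf4. Mice put on the high-fat diet and killed before treatment are named in the series description and were not analysed here.

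Gene symbols came from a table that matched 52083 of the Ensembl gene IDs. The other 3276 IDs held 0.515% of all counts. The annotation at hand is of an older build than the counts, so no coordinates are given. Of the genes, 29250 had a count, and 15274 passed edgeR's filterByExpr with a minimum count of 10, of which 15242 had a symbol. Totals per library ranged from 23743415 to 33257260 counts, and TMM factors from 0.779 (lean 3) to 1.17. CPM values use the totals scaled by TMM. Log2 CPM for plots and spread checks used a prior count of 2. Correlations of log2 CPM between replicates were 0.946 to 0.980. The lowest chi-square per degree of freedom between replicates was 40.7, so mice differed by far more than counting error. Ratios against a group with 1 to 3 counts carry an exact 95% interval for 2 Poisson counts. These intervals and the floor of 3 counts cover counting error only.

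Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test (robust fit) on TMM-scaled counts, 2-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. All 12 samples entered one fit with group as the only term, so that the 3 groups share one estimate of the spread. The comparisons were HFD control against lean, NM-FGF19 against HFD control and NM-FGF19 against lean. The SE of a log2 change is the one implied by its F statistic. The tests, the groups in the fit, the alternatives, 36 gene lists (24 of pathways and 12 of cell type markers) and the rule for naming genes were chosen before the data were examined. Gene lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, over the 34 lists with at least 3 genes tested. With the correlation estimated per list, 0 lists passed in each comparison against 18, 15 and 16, and the lowest adjusted p-values were 0.346, 0.132 and 0.351. A count described as adjusted over the list alone applies the Benjamini-Hochberg method to the edgeR p-values of that list.

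Named genes follow a rule with 3 parts. The first part takes, per comparison, the 6 highest and 6 lowest log2 changes among called genes with a mean of at least 2 CPM, groups that do not overlap and an informative symbol. The second part is a fixed set of genes: Cyp7a1, Cyp8b1, Nr0b2, Fgf15, Fgf21, Klb, Fgfr4, Tnfsf4, Col1a1, Afp, Mki67 and Cidea. The third part takes from each list the 2 called members with the smallest adjusted p in its main direction and 1 in the other, as examples. Any other gene is said to be named after its value was seen. Genes of families with near-identical copies are described as uncertain, because the handling of reads that fit several copies is not given.

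The HFD control libraries serve both the diet and the treatment comparison. Their shared chance values were simulated with 20 draws of unchanged groups, and the comparison was repeated with the 4 libraries split in 6 ways. Alternatives were DESeq2 1.42.0, limma voom, size factors of the RLE kind, library totals alone, no filter on low counts, a stricter filter (1 CPM in at least 4 samples), a fit without the robust option, only the 2 groups compared, the replicate number as a block, and leaving out each library. After seeing the data, 3 more were added: leaving out the 2 libraries farthest from their groups (lean 3 and HFD control 3), sample quality weights, and a clock score as a covariate.

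The scripts were tested on simulated data for NM-FGF19 against HFD control, with 15274 genes drawn from the real means and library sizes and 50 genes each changed 1.5-, 2-, 4- and 8-fold. The changed genes were picked among those with a mean of at least 1 CPM. The edgeR test called 4, 46, 92 and 90% of them, and 6 of its 122 calls were on unchanged genes. Camera called the raised list at an adjusted p of 2.86e-20 with the preset correlation and 0.000263 with an estimated one. With the preset correlation it also called 1 of the 33 other lists. Simulated genes were drawn independently, so p-values at the preset correlation were not checked for lists whose genes move together. The raised list was cholesterol synthesis, whose estimated correlation in the real data was 0.77 in each comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.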

Results

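Liver RNA was sequenced from 12 male C57BL/6NTac mice in 3 groups of 4. Lean mice ate normal chow and received a control mRNA. HFD control mice ate a high-fat diet and received a control mRNA. NM-FGF19 mice ate the same high-fat diet and received mRNA for a non-mitogenic form of FGF19, a gut hormone that represses bile acid synthesis in the liver through the receptor FGFR4 and its partner beta-klotho. The mRNAs were injected weekly for 6 weeks in lipid nanoparticles, and livers were taken 24 hours after the last dose. The labels give 21 weeks of diet before treatment in one place and 28 weeks of feeding in another. They also call the mice 24 weeks old, fewer weeks than the 28 of feeding. Each library is named here by its group and its replicate number in the labels.

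The libraries held 23743415 to 30349156 counted reads in lean mice, 32284438 to 33257260 in HFD control mice and 26809039 to 30014092 in NM-FGF19 mice. A floor of 3 counts corresponded to 0.0792 to 0.153 CPM per library. Mitochondrial genes took 4.85 ± 0.175%, 4.98 ± 0.496% and 4.99 ± 0.528% of counts (mean ± SD, n = 4 each) in lean, HFD control and NM-FGF19 livers. Albumin mRNA (Alb) alone took 4.83 ± 0.514%, 3.69 ± 0.959% and 7.61 ± 1.66% in the same order. The first 2 principal components held 33.7% and 15.6% of the variance. Lean 3 and HFD control 3 lay farthest from their groups on them, and counts without these 2 libraries are given below. Levels are mean CPM ± SD over 4 mice, changes are log2 fold changes ± SE, and adjusted p-values for genes are from edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over 15274 genes. For gene lists they are from limma's camera, with a preset correlation between genes unless an estimated one is named. Camera compares the members of a list with all other genes and does not test the median printed beside it. Its direction can differ from the sign of that median.

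HFD control against lean livers compares the high-fat diet with chow, and the labels say of both groups only that they received control mRNA. The HFD control columns alone are named after mouse OX40L, so a different control mRNA could be part of this comparison. Genes of cholesterol synthesis fell on the high-fat diet. Sqle, whose enzyme makes the first oxygenated sterol precursor, went from 162 ± 78.5 to 1.96 ± 0.526 CPM, a log2 change of −6.36 ± 0.83 (adjusted p = 0.00316, n = 4 per group). Tm7sf2, a sterol reductase gene, changed by −2.01 ± 0.26 (adjusted p = 0.00267), from 113 ± 5.72 to 28 ± 3.25 CPM. Mvk, for mevalonate kinase, changed by −2.28 ± 0.31 (adjusted p = 0.00316). Of 24 genes tested on the cholesterol list, 23 fell and 0 rose, and the same numbers held adjusted over the list alone. The list's median log2 change was −2.15 (adjusted p = 3.8e-21, or 0.346 with an estimated correlation), and with library totals as the only scaling it was −1.82. The count of 23 became 9 without lean 3 and HFD control 3, and 16 with a clock score as a covariate. The list's median was −2.15 and −2.07 in these 2 fits. DESeq2 called 23 and limma voom 21.

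Some genes of fat storage and fatty acid oxidation rose, with neither list passing at an estimated correlation (adjusted p = 0.346 each). Cidea, which encodes a lipid droplet protein nearly silent in lean liver, had 2975 counts in the 4 HFD control libraries against 2 in the 4 lean ones, a CPM ratio of 956 with a 95% counting interval of 264 to 7899 (adjusted p = 0.0317). Its call was lost without any 1 of lean 1, 2, 3 or 4 or HFD control 1 or 3, with adjusted p up to 0.109. Cd36, for a fatty acid transporter, rose from 29.8 ± 4.37 to 193 ± 101 CPM, a log2 change of 2.70 ± 0.34 (adjusted p = 0.00267). Mogat1, for a triglyceride synthesis enzyme, had 360 counts against 2, a ratio of 116 with an interval of 31.8 to 959 (adjusted p = 0.00317). Ehhadh and Acaa1b, peroxisomal oxidation genes driven by PPAR-alpha, rose by 1.80 ± 0.25 and 2.63 ± 0.36 (adjusted p = 0.00285 and 0.00287). Cyp4a14 rose by a fitted 513-fold (adjusted p = 0.0185), from 0.457 ± 0.383 to 244 ± 212 CPM, and Cyp4a10 by 5.20 ± 1.13 (adjusted p = 0.0215). Cyp4a genes are near-identical copies, so their counts are uncertain. The Cyp4a14 call was lost without lean 2, lean 3 or HFD control 3 (adjusted p up to 0.0531), and the Cyp4a10 call without lean 2, lean 3, lean 4 or HFD control 3 (up to 0.0588). Leaving out lean 1 moved the log2 change of Cidea from 9.62 to 12.22, of Cyp4a10 to 6.43 and of Cyp4a14 to 9.65, and Cyp4a14 was at 8.41 without HFD control 4. Mogat1 was at 6.57, 9.22 without lean 2 and 5.92 without HFD control 3, and Cidea at 8.17 without HFD control 3.

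On the list of fatty acid oxidation and PPAR-alpha targets, 12 of 22 genes rose, 0 fell and 10 did not pass, and 14 were higher adjusted over the list alone. The 12 became 5 without lean 2, 5 without lean 3, 6 without lean 4, 4 without HFD control 3 and 3 without both lean 3 and HFD control 3. The median change was 0.66 (adjusted p = 6.05e-10, or 0.346 with an estimated correlation). On the lipid droplet and lipid uptake list, 7 of 18 rose, 0 fell and 11 did not pass, and 12 were higher adjusted over the list alone. The median was 1.28, also with its 2 genes near zero in lean livers set to their counting bound (adjusted p = 1.29e-07, or 0.346 with an estimated correlation). The 7 became 11 without HFD control 2 and 4 without lean 3 and HFD control 3. Among lipoprotein and sterol export genes, Abcg5 and Abcg8, the partners of the sterol exporter into bile, rose by 1.96 ± 0.34 and 1.81 ± 0.32 (adjusted p = 0.00848 each). The other 16 of 18 on that list did not pass. Its median was −0.04 with TMM and 0.24 with library totals alone (adjusted p = 0.807, or 0.904 with an estimated correlation). All 20 lipogenesis genes tested stayed short of the threshold in edgeR. At an unadjusted p under 0.05, 2 were higher and 5 lower, DESeq2 called 2 higher and 4 lower, and voom 1 higher and 0 lower. The lipogenesis median was −0.08, and 0.24 with library totals alone (adjusted p = 0.454, or 0.827 with an estimated correlation).

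At least 50% of the genes on the extracellular matrix, interferon and cell cycle lists rose. Col1a1, for the main fibrillar collagen of scar, rose from 8.85 ± 3.08 to 108 ± 78 CPM, a log2 change of 3.61 ± 0.73 (adjusted p = 0.0162). Col3a1 rose by 3.40 ± 0.57 (adjusted p = 0.00848) and Sparc by 1.71 ± 0.31 (adjusted p = 0.0101). Without HFD control 3, Col1a1 was at 2.99. On the extracellular matrix list, 18 of 27 rose, 0 fell and 9 did not pass, and 22 were higher adjusted over the list alone. The median was 1.73 (adjusted p = 1.04e-14, or 0.346 with an estimated correlation). The 18 became 11 without lean 2 and 7 without lean 3 and HFD control 3. On the interferon response list, 19 of 27 rose, 0 fell and 8 did not pass. Adjusted over the list alone, 23 were higher and 2 lower, the 2 being Mx2 and Stat2, named after their values were seen. Gbp2 rose by 1.99 ± 0.31 (adjusted p = 0.00457) and Oas1a by 2.05 ± 0.32 (adjusted p = 0.00501). The median was 1.43 (adjusted p = 1.41e-12, or 0.346 with an estimated correlation). The 19 became 11 without HFD control 1, 11 without HFD control 3 and 9 without lean 3 and HFD control 3. On the cell cycle list, 12 of 24 rose, 0 fell and 12 did not pass, and 17 were higher adjusted over the list alone. Mcm5, for a replication helicase subunit, rose by 2.01 ± 0.22 (adjusted p = 0.00141), Top2a by 2.39 ± 0.32 (adjusted p = 0.00275) and Mki67, a marker of dividing cells, by 1.95 ± 0.43 (adjusted p = 0.0176). The cell cycle median was 1.45 (adjusted p = 1.27e-11, or 0.346 with an estimated correlation), and 8 rose without lean 3 and HFD control 3.

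Macrophage markers split by type. Cd163 and Timd4, markers of resident Kupffer cells, fell, with log2 changes of −6.08 ± 1.00 and −5.50 ± 0.86 (adjusted p = 0.00848 and 0.00633). Cd163 went from 55.8 ± 16.6 to 0.819 ± 0.392 CPM and Timd4 from 13.9 ± 2.15 to 0.303 ± 0.0689. Of 8 resident Kupffer cell markers, 5 fell, 0 rose and 3 did not pass, and 6 were lower adjusted over the list alone. The other 3 that fell, named after their values were seen, were Clec4f, Vsig4 and Marco. The median was −2.65 (adjusted p = 1.92e-05, or 0.346 with an estimated correlation), and 3 fell without lean 3 and HFD control 3. Gpnmb, raised in macrophages that have taken up lipid, rose by 7.22 ± 0.74 (adjusted p = 0.00149), from 0.297 ± 0.223 to 42.8 ± 31.8 CPM, or by 6.55 without HFD control 3. Itgax rose by 3.26 ± 0.36 (adjusted p = 0.00141) and Cx3cr1 by 3.05 ± 0.32 (adjusted p = 0.00139). On the list of monocyte-derived and lipid-associated macrophage markers, 10 of 14 rose, 1 fell and 3 did not pass, and adjusted over the list alone 11 were higher and 1 lower. Fabp5 was the one that fell, by 2.67 ± 0.62 on the log2 scale (adjusted p = 0.0261). It lost its call without any 1 of lean 2, 3 or 4 or HFD control 1, 2, 3 or 4 (adjusted p up to 0.0765). The list's median was 2.34 (adjusted p = 1.41e-05, or 0.369 with an estimated correlation), and 1.53 to 2.57 with 1 library left out. The 10 became 6 without lean 4 and 7 without lean 3 and HFD control 3.

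Inflammatory cytokine and adhesion genes went both ways. Of 15, 3 rose, 1 fell and 11 did not pass, and adjusted over the list alone 8 were higher and 2 lower. The chemokine gene Ccl2 rose by 3.48 ± 0.77 (adjusted p = 0.0184, and at most 0.0541 with 1 library left out, without lean 4), and Ccl4 by 3.10 ± 0.84 (adjusted p = 0.0386). Cxcl14 fell by 4.13 ± 0.98 on the log2 scale (adjusted p = 0.0286). Ccl4 and Cxcl14 each kept their calls in 3 of 8 fits without 1 library, with adjusted p up to 0.106 and 0.082. Leaving out lean 3 moved Cxcl14 to −2.83, and leaving out lean 4 moved Ccl4 to 4.26. Ccl2 was at 4.17 without lean 2 and 2.66 without HFD control 3. The median was 0.71 (adjusted p = 0.0293, or 0.53 with an estimated correlation). That test missed the threshold without lean 1 (0.253), without HFD control 3 (0.154) and with library totals alone (0.428), and 0 genes were called without lean 3 and HFD control 3. Cfd, an adipocyte marker that encodes complement factor D, rose by 7.72 ± 1.31 (adjusted p = 0.00848), from 0.0465 ± 0.0929 to 10 ± 8.46 CPM, or by 11.24 without lean 2 and 7.08 without HFD control 1.

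Acute phase genes, which hepatocytes switch on under inflammatory cytokines, were mostly lower in HFD control livers. Fgb, for a fibrinogen chain, fell by 2.04 ± 0.38 on the log2 scale (adjusted p = 0.0103), and Orm2 by 2.37 ± 0.44 (adjusted p = 0.0107). Saa3 went the other way and rose by 3.57 ± 0.70 (adjusted p = 0.0139). Without lean 3, Orm2 was at −1.71 and Saa3 at 4.18. Orm and Saa genes have near-identical copies, so their counts are uncertain. Of 19 genes tested, 11 fell, 1 rose and 7 did not pass, and adjusted over the list alone 15 were lower and 1 higher. The median was −1.60 (adjusted p = 1.79e-07, or 0.369 with an estimated correlation). The 11 became 6 without HFD control 1, 5 without HFD control 3 and 5 without lean 3 and HFD control 3. Hepatocyte markers had a median of −0.57, and −0.26 with library totals alone (adjusted p = 0.000553, or 0.346 with an estimated correlation), with 2 of 11 falling, 0 rising and 9 not passing, and 6 lower adjusted over the list alone. The 2 were Ambp at −0.90 ± 0.20 (adjusted p = 0.0185) and Serpina1a at −0.80 (adjusted p = 0.022), a member of a gene family with near-identical copies. The 2 became 1 without lean 2, 1 without lean 4, 0 without HFD control 1, 0 without HFD control 3 and 0 without lean 3 and HFD control 3, and 1 with library totals alone. Of 19 xenobiotic genes 2 rose, 0 fell and 17 did not pass, and adjusted over the list alone 3 were higher and 1 lower. That median was 0.56, 0.35 without lean 3 and HFD control 3 and 0.86 with library totals alone (adjusted p = 0.00181, or 0.376 with an estimated correlation). Cyp3a11, for a drug-oxidising enzyme, rose by 3.82 ± 0.74 (adjusted p = 0.0132). Gsta1, a gene with near-identical copies, had 731 counts against 2, a ratio of 235 with an interval of 64.8 to 1944 (adjusted p = 0.0174, and up to 0.0591 without lean 2 or lean 4). Its log2 change of 7.57 became 10.21 without lean 4 and 5.82 without HFD control 3, and that of Cyp3a11 became 4.45 and 3.19.

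Most bile acid and FGF receptor genes did not pass between the diets. Cyp7a1, for the first enzyme of the classical bile acid pathway, changed by 0.47 ± 0.80 (adjusted p = 0.77). Cyp8b1, for the 12-alpha-hydroxylase that sets the share of cholic acid, changed by −0.06 ± 0.21 (adjusted p = 0.901). Of 15 bile acid synthesis genes, 1 fell, 0 rose and 14 did not pass, and adjusted over the list alone 3 were lower and 1 higher. The median was −0.11 with TMM (adjusted p = 0.184, or 0.726 with an estimated correlation), and −0.28 to −0.01 with 1 library left out. With library totals alone it was 0.17, with 2 genes higher and 0 lower. The 1 that fell with TMM was Cyp27a1, of the alternative pathway, at −0.50 ± 0.14 (adjusted p = 0.0475). It kept its call in only 1 of the 8 fits that left out a lean or an HFD control library, with adjusted p up to 0.155. The 3 and 1 adjusted over the list alone were Cyp27a1, Cyp2c70 and Baat, and Hsd17b4, the last 3 named after their values were seen. Of 14 bile acid transport and nuclear receptor genes, 1 rose, 1 fell and 12 did not pass, the same 1 and 1 when adjusted over the list alone. That median was 0.25 (adjusted p = 0.193, or 0.53 with an estimated correlation), and 0.14 to 0.36 with 1 library left out, when 1 to 4 rose; it was 0.54 with library totals alone, with 4 higher and 0 lower. The transporter gene Abcc3 rose by 2.23 ± 0.37 (adjusted p = 0.00772). Slc10a1, for the bile acid uptake transporter, fell by 0.84 ± 0.24 on the log2 scale (adjusted p = 0.05, just under the threshold before rounding). It kept its call in 2 of the 8 fits without 1 lean or HFD control library, with adjusted p up to 0.114. On the FGF receptor list, Spred1, for an inhibitor of receptor signalling, rose by 0.83 ± 0.12 (adjusted p = 0.00326), and Fgfr1 fell by 1.64 ± 0.31 on the log2 scale (adjusted p = 0.0117). Fgfr3 was at −0.63 ± 0.18 (adjusted p = 0.0465) and kept its call in 2 of 8 fits without 1 library, with adjusted p up to 0.122. These were the 1 higher and 2 lower of 21, 18 did not pass, and adjusted over the list alone 2 were higher and 3 lower. The median was 0.03 (adjusted p = 0.807, or 0.909 with an estimated correlation). With library totals alone it was 0.33, with 4 higher and 1 lower. Fgfr4 changed by −0.56 (adjusted p = 0.146, and 0.0229 without HFD control 2, in a range of 0.0229 to 0.564 over 20 alternatives), and Klb, for beta-klotho, by −0.34 (adjusted p = 0.428). Nr0b2, the nuclear receptor target of bile acids, changed by −0.18 (adjusted p = 0.872), Fgf21 by 1.44 (adjusted p = 0.4) and Afp by −0.39 (adjusted p = 0.376).

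Across all genes 770 rose and 502 fell, or 1272 of 15274, and 547 and 245 of them changed at least 2-fold. An unadjusted p under 0.05 was met by 3752. The lowest log2 changes by the naming rule, besides Sqle, Cd163 and Timd4, were in Trat1, Tmc5 and Igdcc4. Trat1, for a T cell receptor adaptor, stood at −7.04 ± 1.61 (adjusted p = 0.0257), Tmc5 at −5.24 ± 1.24 (adjusted p = 0.0272) and Igdcc4 at −5.07 ± 1.13 (adjusted p = 0.0214). Their calls were lost without HFD control 1, 3 or 4, and that of Tmc5 also without lean 3 or 4, with adjusted p up to 0.0851, 0.0842 and 0.0667. Their sizes rest in part on lean 3: without it Trat1 was at −4.23, Tmc5 at −4.26 and Igdcc4 at −2.79. Without HFD control 2, Trat1 was at −8.01 and Tmc5 at −7.34. The total of 1272 became 635 without lean 2, 739 without lean 4, 641 without HFD control 1, 537 without HFD control 3 and 480 without lean 3 and HFD control 3. With library totals alone, 2383 rose and 228 fell, 91.3% higher against 60.5% with TMM. With that scaling the median log2 change of all genes was 0.29, against −0.02 with TMM, and directions here are relative to TMM. The median SE of a log2 change was 0.222, so small changes were not detectable in most genes.

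**Figure D1:**
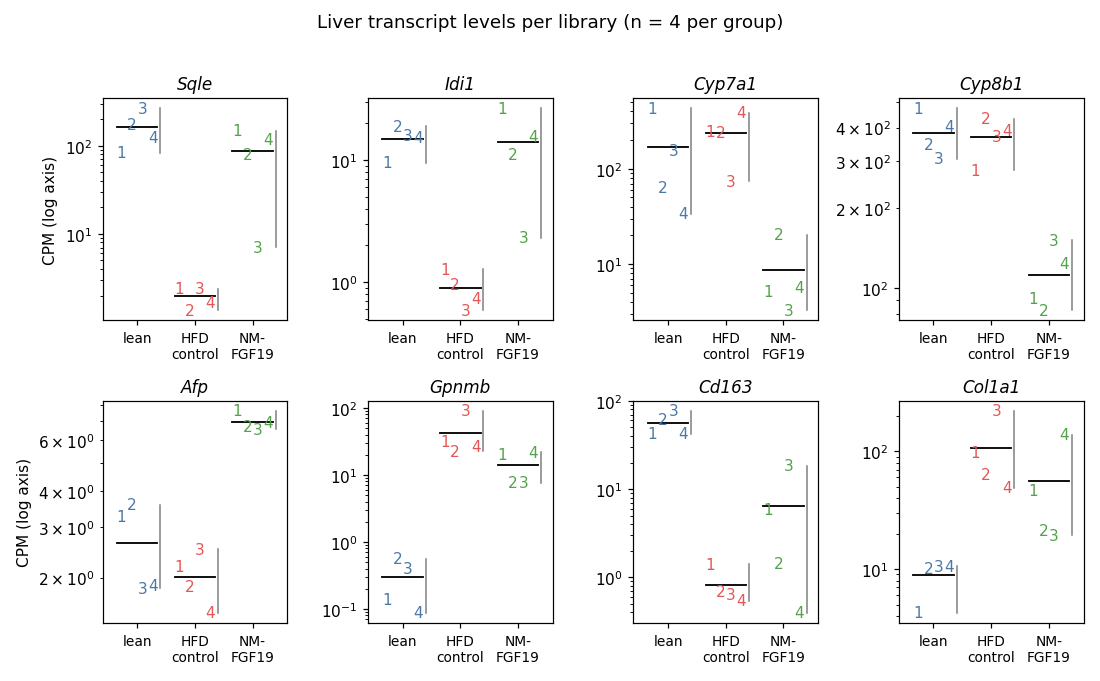
CPM on a log scale of 8 genes in the 12 libraries, in panels by gene and columns by group. Points are libraries with their replicate numbers, the black line is the group mean and the grey line the range; Sqle is at 1.96 CPM on average in HFD control livers against 162 in lean and 88 in NM-FGF19 livers.

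NM-FGF19 against HFD control livers compares FGF19 mRNA with control mRNA in mice on the same diet. The HFD control columns are named after mouse OX40L, so an effect of that control mRNA could be part of this comparison too. Genes of cholesterol synthesis rose. Sqle went from 1.96 ± 0.526 to 88 ± 60.7 CPM, a log2 change of 5.48 ± 0.80 (adjusted p = 0.0161, n = 4 per group). Idi1, for an isomerase of isoprene units, rose from 0.888 ± 0.295 to 13.9 ± 10.1 CPM (3.96 ± 0.61, adjusted p = 0.0174). Stard4, for a sterol carrier, rose from 44.5 ± 7.99 to 135 ± 40 CPM (1.60 ± 0.23, adjusted p = 0.00786). Cyp51, Msmo1, Lss and Mvk rose by 3.44 ± 0.58, 2.71 ± 0.49, 2.39 ± 0.39 and 2.10 ± 0.31 (adjusted p = 0.0294, 0.0357, 0.0246 and 0.0148). Of 24 genes tested, 12 rose, 0 fell and 12 did not pass, and 23 were higher adjusted over the list alone. The median log2 change was 2.11 (adjusted p = 1.64e-31, or 0.145 with an estimated correlation).

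The count of cholesterol genes past the threshold depended on single libraries while the median did not. The 12 became 1, 6, 1 and 1 without HFD control 1, 2, 3 and 4, and 2, 4, 21 and 5 without NM-FGF19 1, 2, 3 and 4. The median stayed between 1.85 and 2.39 in these 8 fits. Without lean 3 and HFD control 3 the count was 1 and the median 2.08. DESeq2 called 21 and voom 5. NM-FGF19 3 was the low library, with Sqle at 7.1 CPM. The Stard4 call held in all 8 fits. The calls of Sqle (adjusted p up to 0.0819) and Idi1 (up to 0.0885) were lost without HFD control 1, 3 or 4, and that of Sqle also without NM-FGF19 1. Mvk lost its call without HFD control 1, 3 or 4 or NM-FGF19 1 or 2 (up to 0.0779). Cyp51, Msmo1 and Lss kept theirs only without NM-FGF19 3, with adjusted p up to 0.124, 0.149 and 0.1 in the other 7 fits.

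Of the bile acid synthesis genes, edgeR called only Cyp8b1 in treated livers. It fell by 1.72 ± 0.22 on the log2 scale (adjusted p = 0.00699), from 368 ± 65.5 to 112 ± 31.5 CPM, and its call held in all 8 fits without 1 library of either group. Cyp7a1, which FGF19 signalling is known to repress, was at 8.59 ± 7.84 CPM against 237 ± 128, a log2 difference of −4.79 ± 0.95 that just missed the threshold (adjusted p = 0.0672). It passed in 6 of 20 other settings, among them DESeq2 and voom, with adjusted p from 1.53e-05 to 0.238 over the 20. Of 15 genes tested, 1 fell, 0 rose and 14 did not pass, and 3 were lower adjusted over the list alone. These 3 were Cyp7a1, Cyp8b1 and Cyp27a1. The list's median was −0.12 (adjusted p = 0.00813, or 0.535 with an estimated correlation). With 1 library left out it ran from −0.23 to 0.00, and the list test missed the threshold without HFD control 2 (0.268), HFD control 4 (0.0641) or NM-FGF19 4 (0.147). Without lean 3 and HFD control 3, 1 gene fell. Among the 14 bile acid transport and nuclear receptor genes, edgeR, DESeq2 and voom each called 0, and 2 were higher and 4 lower at an unadjusted p under 0.05. That list's median was −0.08 (adjusted p = 0.628, or 0.824 with an estimated correlation). Nr0b2 changed by 0.71 (adjusted p = 0.774).

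Fat storage and detoxification genes were lower as lists. On the lipid droplet and lipid uptake list edgeR and voom called 0 of 18, DESeq2 called 6 lower, and 11 were lower at an unadjusted p under 0.05. Adjusted over the list alone, 10 were lower and 0 higher. The median was −0.82, and −0.50 without lean 3 and HFD control 3 (adjusted p = 2.26e-08, or 0.313 with an estimated correlation). Cidea was at −3.04 (adjusted p = 0.558). On the xenobiotic list, 1 of 19 fell, 0 rose and 18 did not pass, and 9 were lower adjusted over the list alone. The mean was −1.24 (adjusted p = 1.16e-08, or 0.145 with an estimated correlation). The median ran from −1.12 to −0.66 with 1 library left out, and was −0.66 without lean 3 and HFD control 3. The 1 was Gsta2, a gene with near-identical copies, at −3.91 ± 0.65 (adjusted p = 0.0266). Ephx1, for microsomal epoxide hydrolase, fell by 1.80 ± 0.25 on the log2 scale (adjusted p = 0.00786), from 428 ± 161 to 123 ± 31.3 CPM. It was the 1 of 13 antioxidant response genes to fall, with 0 rising and 12 not passing, and 4 were lower adjusted over the list alone. That median was −0.35 (adjusted p = 1.87e-06, or 0.145 with an estimated correlation). The 4, of which all but Ephx1 are named after their values were seen, were Ephx1, Nqo1, Gclm and Ugdh. On the fatty acid oxidation list Acaa1b fell by 2.14 ± 0.36 on the log2 scale (adjusted p = 0.0221), 0 rose and 21 did not pass, and 4 were lower adjusted over the list alone. The 4 were Acaa1b, Ehhadh, Acadm and Acot1, the last 2 named after their values were seen; Acot1 has a near-identical copy. The median was −0.35 (adjusted p = 0.000984, or 0.598 with an estimated correlation), −0.42 to −0.16 with 1 library left out, and −0.16 without lean 3 and HFD control 3. The calls of Gsta2 and Acaa1b were lost without HFD control 1, 3 or 4 or NM-FGF19 1, 2 or 4, with adjusted p up to 0.112 and 0.0802. Without lean 3 and HFD control 3, 2 xenobiotic, 1 antioxidant and 1 fatty acid oxidation gene fell.

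The extracellular matrix, cell cycle and monocyte-derived macrophage lists had negative medians, with 0 genes called by edgeR, DESeq2 or voom in each. On the extracellular matrix list the median was −0.42, −0.78 to −0.14 with 1 library left out, and −0.15 without lean 3 and HFD control 3 (adjusted p = 3.33e-05, or 0.599 with an estimated correlation). At an unadjusted p under 0.05, 2 of its 27 genes were lower and 0 higher, and 0 passed adjusted over the list alone. Col1a1 was at −0.94 ± 0.66 (adjusted p = 0.752). The cell cycle median was −0.50, −0.82 to −0.17 with 1 library left out, and −0.17 without those 2 libraries (adjusted p = 0.000169, or 0.535 with an estimated correlation), with 1 of 24 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. Mki67 was at −0.64 (adjusted p = 0.71). The median of monocyte-derived and lipid-associated macrophage markers was −0.70, and −0.26 without the same 2 libraries (adjusted p = 0.000194, or 0.535 with an estimated correlation). Of these markers 6 of 14 were lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. Resident Kupffer cell markers had a median of 0.79 (adjusted p = 0.305, or 0.824 with an estimated correlation), 0.27 to 1.32 with 1 library left out, and 1.31 without lean 3 and HFD control 3. Of them edgeR and voom called 0 of 8 and DESeq2 called 3 higher, as many as at an unadjusted p under 0.05. Timd4, Marco and Cd163 were the 3 higher adjusted over the list alone, Marco being named after its value was seen.

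No FGF receptor gene or immediate target was called by edgeR or voom. The median of the 21 was 0.32, and 0.20 with library totals alone (adjusted p = 3.1e-05, or 0.132 with an estimated correlation). DESeq2 called 2 higher, and 8 were higher and 0 lower at an unadjusted p under 0.05. When adjusted over the list alone, 5 were higher: Fgfr2, Dusp4, Spry4, Spred2 and Etv5, of which all but Spred2 are named after their values were seen. Klb changed by 0.33 (adjusted p = 0.771), Fgfr4 by 0.07 (adjusted p = 0.975) and Fgf21 by −0.76 (adjusted p = 0.894). Afp, for the fetal serum protein alpha-fetoprotein, rose from 2.02 ± 0.432 to 6.96 ± 0.459 CPM (1.78 ± 0.25, adjusted p = 0.00786). It was the 1 of 11 oncofetal and tumour-associated genes called. That list's median was −0.16, and 0.36 without lean 3 and HFD control 3 (adjusted p = 0.533, or 0.824 with an estimated correlation). Hepatocyte markers had a median of 0.26, and 0.13 with library totals alone (adjusted p = 0.000176, or 0.145 with an estimated correlation). Of those 11, edgeR and voom called 0, DESeq2 called 4 higher and 5 were higher at an unadjusted p under 0.05. There were 4 higher adjusted over the list alone: Alb, Ahsg, Serpina1a and Serpina1b, all but Serpina1a named after their values were seen.

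The genes that fell most by the naming rule were Cfd, Gsta2, Tsku, Csad, Adam11 and Nat8f5. Csad, for an enzyme that makes taurine, the main bile acid conjugate in mice, fell by 3.13 ± 0.32 on the log2 scale (adjusted p = 0.00487), from 156 ± 45.2 to 17.7 ± 6.55 CPM. Tsku, for a secreted liver protein that affects cholesterol handling, fell by 3.15 ± 0.41 (adjusted p = 0.00786), from 149 ± 47.2 to 16.8 ± 7.19 CPM. Nat8f5, of a family with near-identical copies, fell by 2.48 ± 0.33 (adjusted p = 0.00745). Cfd stood at −6.94 ± 1.18 (adjusted p = 0.0294) and Adam11 at −2.61 ± 0.46 (adjusted p = 0.0318). Wnk4, for a kinase of ion transport, rose by 2.41 ± 0.37 (adjusted p = 0.0148). The calls of Csad, Tsku, Nat8f5, Cyp8b1, Ephx1, Stard4 and Afp held in all 8 fits without 1 library. Wnk4 lost its call without HFD control 1, 3 or 4 or NM-FGF19 1 (adjusted p up to 0.0718). Cfd lost it without HFD control 1, 3 or 4 or NM-FGF19 1, 2 or 3 (up to 0.125), and Adam11 in all but the fit without NM-FGF19 3 (up to 0.122), where it was at −3.34. Cfd was at −9.29 without NM-FGF19 4 and −6.30 without HFD control 1.

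Across all genes 43 rose and 23 fell, 66 in all, and 34 and 19 of these changed at least 2-fold. An unadjusted p under 0.05 was met by 1367. The total of 66 became 18 without HFD control 1, 22 without HFD control 3, 21 without HFD control 4, 18 without NM-FGF19 1, 25 without NM-FGF19 2 and 41 without NM-FGF19 4. Without lean 3 and HFD control 3 it was 38. DESeq2 called 289 genes, all 66 among them. With library totals alone 26 rose and 30 fell, 46.4% higher against 65.2% with TMM, and the median of all genes shifted by −0.13. Simulated data for this comparison gave calls for 4, 46, 92 and 90% of genes changed 1.5-, 2-, 4- and 8-fold, so changes under 2-fold were mostly not detectable. The changed genes had a mean of at least 1 CPM and were drawn independently, so these shares may be too high for the real data. On the cholesterol list, with a median log2 change of 2.11, edgeR called 12 of 24.

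**Figure D2:**
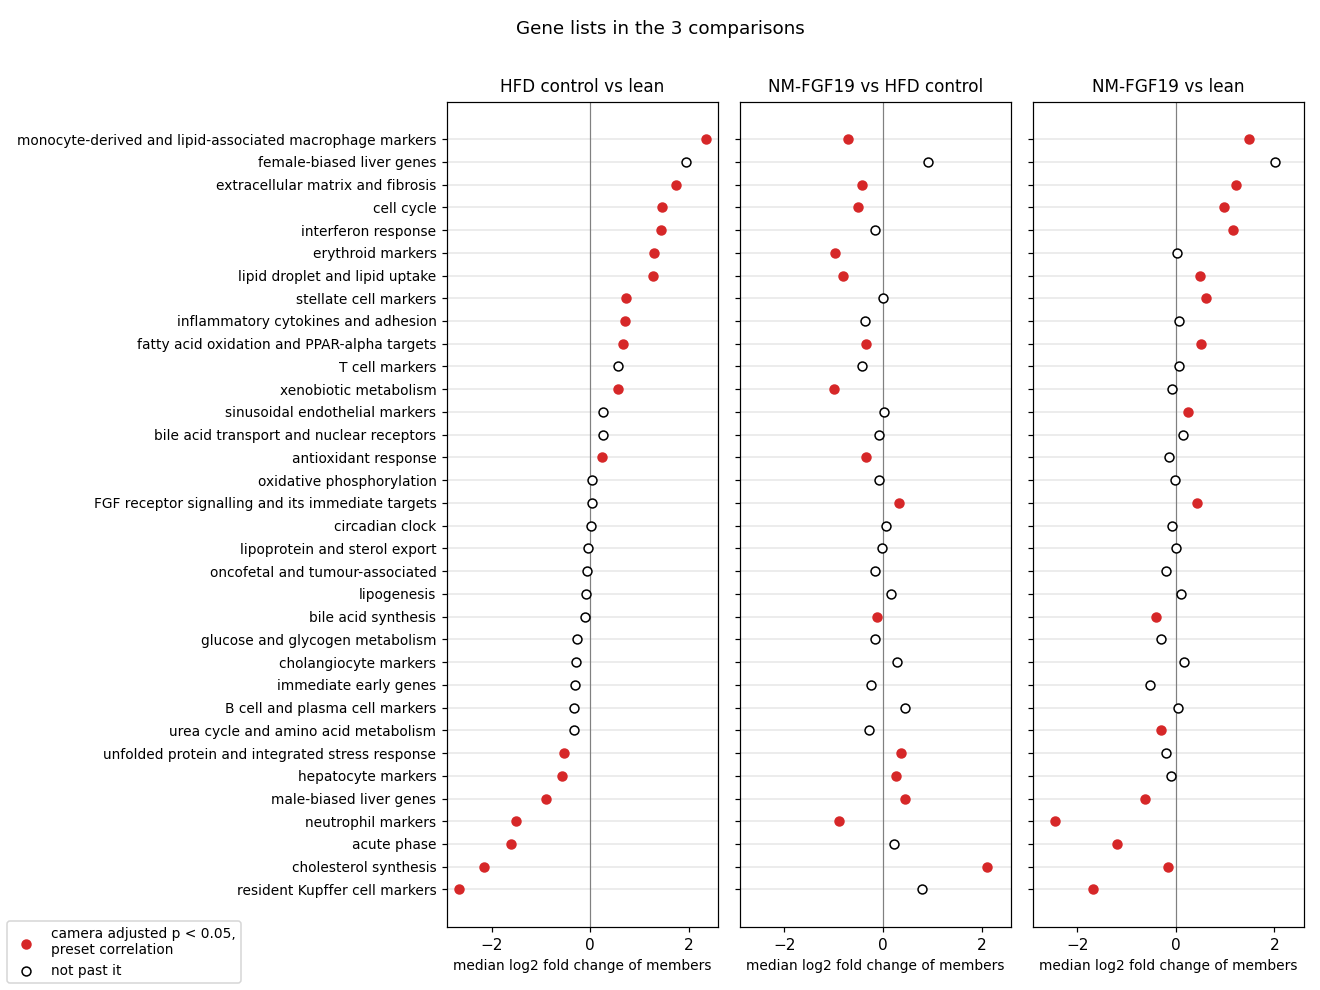
Median log2 fold change of the members of 34 gene lists in the 3 comparisons, 1 panel each, with lists in order of the diet comparison. Filled red points passed camera's adjusted threshold with the preset correlation and open points did not; cholesterol synthesis is at −2.15, 2.11 and −0.15, and moves to 0.04 against lean with library totals alone.

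NM-FGF19 against lean livers shows what still differed from chow-fed liver, with diet and mRNA both changed. Of 15 bile acid synthesis genes, 3 were lower than in lean livers. Cyp8b1 fell by 1.77 ± 0.22 on the log2 scale (adjusted p = 0.00324, n = 4 per group). Cyp27a1, which starts the alternative pathway, fell by 1.16 ± 0.14 (adjusted p = 0.00324), from 593 ± 66.1 to 265 ± 20.9 CPM. Cyp7a1 fell by 4.32 ± 0.93 (adjusted p = 0.0489), from 171 ± 181 to 8.59 ± 7.84 CPM, and lost its call without lean 1, 2 or 3 or NM-FGF19 1, 3 or 4 (adjusted p up to 0.133). Cyp7a1 was at −3.30 without lean 1 and −5.17 without NM-FGF19 2. Besides these 3, 0 rose and 12 did not pass, and 5 were lower adjusted over the list alone. The other 2, named after their values were seen, were Baat and Slc27a5. The median was −0.39, and −0.24 with library totals alone (adjusted p = 6.34e-05, or 0.351 with an estimated correlation), and 3 fell without lean 3 and HFD control 3. On the FGF receptor list, Spred1 rose by 1.11 ± 0.12 (adjusted p = 0.00208) and Spred2 by 0.76 ± 0.14 (adjusted p = 0.0213, and up to 0.0585 without lean 1 or 2). The other 19 of 21 did not pass, and adjusted over the list alone 7 were higher and 1, Fgfr1, lower. The median was 0.43 (adjusted p = 0.000922, or 0.351 with an estimated correlation), and 0.25 to 0.56 with 1 library left out. Afp rose by 1.39 ± 0.25 (adjusted p = 0.0196, and up to 0.0629 without lean 4 or NM-FGF19 1 or 4).

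Cholesterol synthesis genes lay near lean levels in median. EdgeR and voom called 0 of the 24, DESeq2 called 1 lower, and 1 was lower at an unadjusted p under 0.05. Adjusted over the list alone 0 passed. The list, with a median of −0.15, passed the list test as lower (adjusted p = 0.019, or 0.744 with an estimated correlation). Its median was 0.04 with library totals alone, and the list test's direction turned to higher without NM-FGF19 3 (adjusted p = 0.181). The list test also missed the threshold without lean 2 (0.0957) or lean 4 (0.0532).

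The interferon response and cell cycle lists had positive medians against lean, with a minority of genes called. Ifi27l2b and Ifi44, interferon-induced genes, rose by 2.99 ± 0.44 and 2.84 ± 0.42 (adjusted p = 0.0122 each), and Oas1a by 2.22 ± 0.32 (adjusted p = 0.00937). Of 27 interferon response genes 8 rose, 0 fell and 19 did not pass, and 24 were higher adjusted over the list alone. The median change was 1.15 and the mean 1.16 (adjusted p = 2.02e-16, or 0.351 with an estimated correlation). The 8 became 5 without lean 1, 3 without lean 3, 3 without lean 4, 4 without NM-FGF19 1, 4 without NM-FGF19 4 and 5 without lean 3 and HFD control 3. Mcm5 rose by 1.77 ± 0.22 (adjusted p = 0.00324) and Mcm6 by a fitted 2.83-fold (adjusted p = 0.0122). Of 24 cell cycle genes 5 rose, 0 fell and 19 did not pass, and 12 were higher adjusted over the list alone. The other 3 that rose, named after their values were seen, were Mcm2, Mcm3 and Top2a. The median was 0.97 (adjusted p = 3.84e-08, or 0.351 with an estimated correlation). The 5 became 3 without lean 2, 2 without lean 4, 2 without NM-FGF19 4 and 6 without lean 3 and HFD control 3.

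Gpnmb rose by 5.63 ± 0.73 (adjusted p = 0.00795), Itgax by 2.64 ± 0.35 and Cx3cr1 by 2.34 ± 0.32 (adjusted p = 0.00588 each). With Ccr2, named after its value was seen, they made 4 of 14 monocyte-derived and lipid-associated macrophage markers that rose, with 0 falling and 10 not passing. Without lean 3 and HFD control 3, 6 rose. When adjusted over the list alone, 9 were higher and 1, Fabp5, lower. The median was 1.48 (adjusted p = 0.000752, or 0.541 with an estimated correlation). Resident Kupffer cell markers had a median of −1.68 (adjusted p = 1.89e-07, or 0.351 with an estimated correlation). EdgeR called 0 of 8, voom 3 lower and DESeq2 5 lower, and 5 were lower at an unadjusted p under 0.05 and adjusted over the list alone. Camp and Ngp, for neutrophil granule proteins, fell by 3.91 ± 0.61 (adjusted p = 0.0122) and 4.19 ± 0.78 (adjusted p = 0.0227). They were 2 of the 3 of 9 neutrophil markers that fell, with Ltf, named after its value was seen, while 0 rose and 6 did not pass; 8 were lower adjusted over the list alone. The median was −2.45 (adjusted p = 5.22e-07, or 0.351 with an estimated correlation), and the 3 became 1 without lean 2 or without NM-FGF19 1, 2 or 3, and 2 without lean 3 and HFD control 3. Ngp lost its call without lean 2 or without any 1 of NM-FGF19 1, 2, 3 or 4 (adjusted p up to 0.0675), and was at −3.56 without lean 3. Neutrophil markers were also lower in HFD control than in lean livers (median −1.51, adjusted p = 0.00624, or 0.436 with an estimated correlation). There 1 of 9, Camp, was called, at −2.41 (adjusted p = 0.018). Between NM-FGF19 and HFD control the median was −0.90 (adjusted p = 0.00124, or 0.527 with an estimated correlation), with 0 called.

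Vnn1, a PPAR-alpha target, and Cyp4a31, one of the near-identical Cyp4a copies, rose by 3.55 ± 0.58 and 3.49 ± 0.59 (adjusted p = 0.0187 each). They were the 2 of 22 fatty acid oxidation genes called, with 0 lower and 20 not passing, and 6 were higher adjusted over the list alone (median 0.51, 0.27 with a clock score as a covariate, adjusted p = 6.13e-07, or 0.351 with an estimated correlation). The Vnn1 call was lost without lean 3 or NM-FGF19 4 (adjusted p up to 0.0528) and the Cyp4a31 call without lean 2 or 4 (up to 0.053). Cd36 rose by 1.73 ± 0.33 (adjusted p = 0.0247) and Vldlr, for a lipoprotein receptor, by 4.04 ± 0.89 (adjusted p = 0.0496). They were the 2 of 18 lipid droplet genes called, with 0 lower and 16 not passing, and 3 were higher adjusted over the list alone, the other being Mogat1 (median 0.50, 0.23 to 0.62 with 1 library left out, adjusted p = 0.0351, or 0.744 with an estimated correlation). That list test missed the threshold without lean 1 (0.0588), lean 2 (0.0817), lean 4 (0.0608), NM-FGF19 2 (0.0525) or NM-FGF19 4 (0.205), and with library totals alone (0.244). Both calls were lost without any 1 lean library or without NM-FGF19 1 or 4, and that of Cd36 held without NM-FGF19 2 or 3 (adjusted p up to 0.0764), while that of Vldlr held only without NM-FGF19 3 (up to 0.117). Vldlr was at 3.14 without NM-FGF19 4.

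On the extracellular matrix list, Col3a1 and Mmp2 rose by 2.54 ± 0.55 (adjusted p = 0.0482) and 1.76 (adjusted p = 0.0433), 0 fell and 25 did not pass, while 20 were higher adjusted over the list alone. The median was 1.23, and 0.77 to 1.46 with 1 library left out (adjusted p = 9.91e-12, or 0.351 with an estimated correlation). Both calls were lost without any 1 lean library or without NM-FGF19 1 or 4, with adjusted p up to 0.106 and 0.104, and 1 gene rose without lean 3 and HFD control 3. Col3a1 was at 1.73 without NM-FGF19 4. On this list DESeq2 called 17 genes higher, voom 0, and edgeR with library totals alone 10. Col1a1 was at 2.67 ± 0.70 (adjusted p = 0.0897) and Mki67 at 1.31 (adjusted p = 0.136). Cidea had 290 counts against 2, a CPM ratio of 117 with a 95% counting interval of 32.1 to 971 (adjusted p = 0.221). DESeq2 called all 3. On the acute phase list Orm2 fell by 2.58 ± 0.44 on the log2 scale (adjusted p = 0.0187) and Orm3 by 1.65 (adjusted p = 0.0224), both from a family of near-identical copies. With Saa1, named after its value was seen and likewise of a copied family, 3 of 19 fell, 0 rose and 16 did not pass, and adjusted over the list alone 14 were lower and 1, Saa3, higher. The median was −1.20, and −0.74 without lean 3 and HFD control 3 (adjusted p = 2.3e-07, or 0.351 with an estimated correlation). The 3 became 6 without lean 1, 1 without lean 2, lean 3, lean 4 or NM-FGF19 4, 0 without NM-FGF19 1, and 1 without lean 3 and HFD control 3. Orm2 lost its call without NM-FGF19 1 or 4 (adjusted p up to 0.063), and was at −1.93 without lean 3.

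Among the lowest genes by the naming rule, Nat8f5 fell by 2.94 ± 0.34 on the log2 scale (adjusted p = 0.00297) and Ptgds, for prostaglandin D synthase, by 3.42 ± 0.58 (adjusted p = 0.0166), and both kept their calls without any 1 library of either group. Slc13a5, for a citrate transporter, and Isyna1, for inositol synthesis, stood at −2.82 ± 0.59 (adjusted p = 0.0433) and −2.70 ± 0.53 (adjusted p = 0.037). Slc13a5 lost its call without lean 2, 3 or 4 or any 1 of the NM-FGF19 libraries (adjusted p up to 0.107), and Isyna1 in 5 of 8 such fits, without lean 2 or any 1 of the NM-FGF19 libraries (up to 0.0947). Without lean 3, Slc13a5 was at −1.95 and Isyna1 at −1.74. Bhmt, for a betaine-using methyltransferase, fell by 1.75 ± 0.28 (adjusted p = 0.0122) as the only 1 of 25 urea cycle and amino acid genes called. That list's median was −0.31 (adjusted p = 0.000423, or 0.661 with an estimated correlation), −0.48 to −0.21 with 1 library left out, and −0.11 with library totals alone.

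Across all genes 154 rose and 74 fell, 228 in all, and 118 and 49 of these changed at least 2-fold. An unadjusted p under 0.05 was met by 2557. The total of 228 became 87 without lean 2, 119 without lean 3, 95 without lean 4, 71 without NM-FGF19 1, 67 without NM-FGF19 4 and 125 without HFD control 1. Without lean 3 and HFD control 3 it was 229, of which 156 were among the 228. With library totals alone 346 rose and 52 fell, 86.9% higher against 67.5% with TMM. The median log2 change of all genes was then 0.17, against −0.01 with TMM.

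The diet and treatment comparisons were then set side by side. Of the 66 genes that changed with treatment, 43 had also changed with diet, and all 43 went the opposite way. Diet had lowered 30 of these, 12 of them cholesterol synthesis genes, and treatment raised them. It had raised the other 13, which treatment lowered. The remaining 23 treatment genes were not called with diet. Of the 43, 41 were not called between NM-FGF19 and lean livers. Independent lists of these sizes would share 1.41 and 1.16 genes in the 2 directions, and simulated unchanged groups shared at most 1 in 20 draws. These draws called 0 genes raised and at most 1 lowered by diet, so they could share almost none and say little about lists of this length. With the HFD control libraries split between the comparisons, 2 in each, few genes were called in both. Over 6 splits, 0 to 6 genes were raised by diet and then lower, and 0 to 3 lowered and then higher.

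Across genes, which are not independent replicates, the diet and treatment log2 changes had a Pearson r of −0.55. Both comparisons use the HFD control libraries, so a negative r arises with no effect. Simulated unchanged groups gave a mean r of −0.487 (−0.510 to −0.467 in 20 draws). The covariance was −0.205 against −0.0642 simulated, a difference of −0.141. With the 4 HFD control libraries split between the comparisons, r lay between −0.374 and −0.172 in 6 splits, with a median of −0.337. Of genes raised by diet, 91.0% had a negative treatment change, and of genes lowered by diet, 91.0% had a positive one, with genes chosen on the HFD control libraries that both comparisons share. In the splits these shares were 59.8 to 90.4% and 73.9 to 100%.

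**Figure D3:**
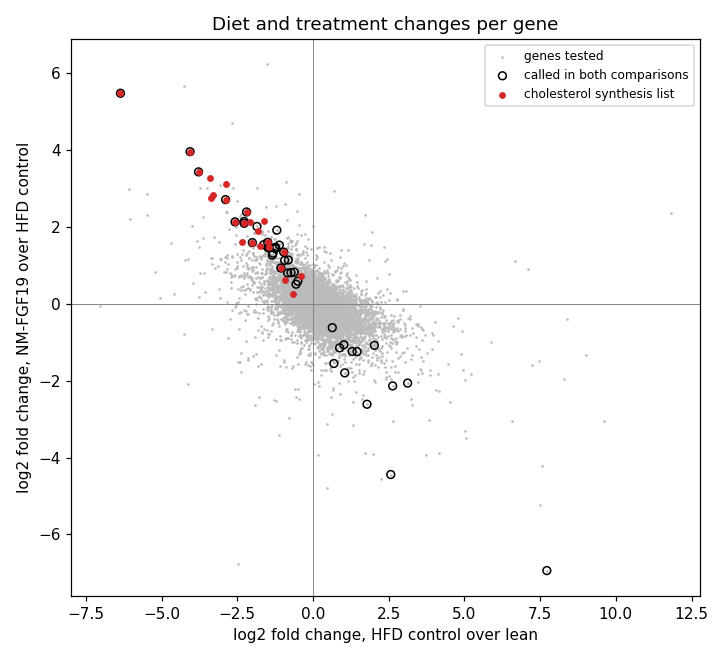
Log2 fold change of HFD control against lean (x axis) and of NM-FGF19 against HFD control (y axis) for each gene tested. Grey points are all genes, black open circles the 43 called in both comparisons and red points the cholesterol synthesis list; r is −0.55, and −0.487 in simulated unchanged groups that share the HFD control libraries.

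Clock genes spread widely among mice of one group. Dbp, a clock output gene, spanned 28.2-fold among the 4 lean livers, Per3 66.9-fold, Npas2 49.1-fold and Arntl, a core clock activator, 36.8-fold. These genes were chosen after their values were seen. In HFD control livers Arntl spanned 8.96-fold and in NM-FGF19 livers 8.77-fold. Of 19 clock genes edgeR, DESeq2 and voom called 0 in each of the first 2 comparisons. In the diet comparison 2 were lower at an unadjusted p under 0.05, and in the treatment comparison 1 was higher. With a clock score as a covariate, chosen after seeing the data, the diet comparison called 461 genes, 422 of them among the 1272. Its counts went from 12 to 5 on the cell cycle list, 19 to 9 for interferon response, 18 to 10 for extracellular matrix, 12 to 5 for fatty acid oxidation and 7 to 4 for lipid droplets. They went from 10 to 5 for monocyte-derived macrophage markers, and of genes that fell, from 5 to 2 for Kupffer cell markers and 11 to 4 for acute phase. The list medians moved less than the counts. They went from 1.45 to 1.51 for cell cycle, 1.43 to 1.26 for interferon response and 1.73 to 1.83 for extracellular matrix. Fatty acid oxidation went from 0.66 to 0.55, lipid droplets from 1.28 to 1.25 and monocyte-derived macrophage markers from 2.34 to 2.19. Kupffer cell markers went from −2.65 to −2.43 and acute phase genes from −1.60 to −1.07. The treatment comparison called 85, with 63 of the 66 among them, and NM-FGF19 against lean called 109, with 98 of the 228 among them.

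**Figure D4:**
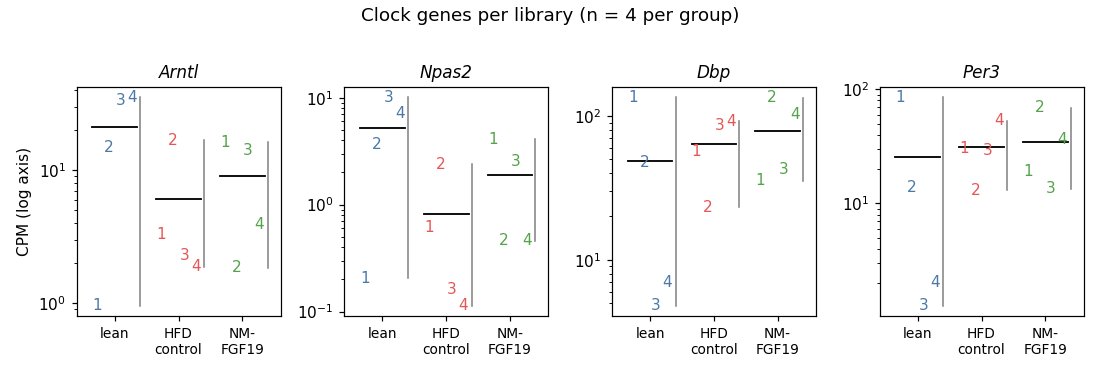
CPM on a log scale of Arntl, Npas2, Dbp and Per3 in the 12 libraries, in columns by group. Points are libraries with their replicate numbers, the black line is the group mean and the grey line the range; Per3 spans 66.9-fold in lean, 4.06-fold in HFD control and 5.12-fold in NM-FGF19 livers.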

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

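The hepatocyte share and library scaling tests in this part, and the fits with a clock score or without lean 3 and HFD control 3, were chosen only after the result was seen; the tests of single libraries, time of day and sample splits, and what clock phase would predict, were set out before it.

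A sample was picked out where its log2 CPM for a named gene lay far from the other 3 of its group, by the ratio of its gap to the group's range. Of 315 groups of values, for 100 genes and for 5 measures of each library, 20 were picked out, and chance alone picks about 1 in 20, or 15.75. In lean livers the ratio was 1 for Cidea (lean 1), Cfd (lean 2), Gsta1 (lean 4) and Mogat1 (lean 2), each with a few counts in that library and 0 in the other 3. Lean 1 was high for Cyp4a10 (0.860; 14.0 against 1.89 to 2.51 CPM) and low for Col1a1 (0.938; 4.25 CPM, with the highest at 10.6). Lean 2 was high for Timd4 (0.850) and low for Vldlr (0.913). Lean 3 was high for Cyp17a1 (0.987; 126 against 26.9 to 27.4 CPM) and low for Lrat (0.938). HFD control 3 was the lowest of its group for Klb (0.854), Slc10a1 (0.858) and Abcg8 (0.923). NM-FGF19 3 was low for the cholesterol genes Mvk (0.840), Msmo1 (0.886) and Lss (0.858). NM-FGF19 4 was high for Mki67 (0.883), Mogat1 (0.858) and Vnn1 (0.864) and low for Wnk4 (0.907).

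The counts of called genes exceeded what other splits of the same mice gave. Of the 35 splits of the 8 samples in each comparison, 1, the real one, reached the real count. For the diet the counts were 1272 and at most 0 in another split. For NM-FGF19 against HFD control they were 66 and at most 19, and for NM-FGF19 against lean 228 and at most 1. The real split can be no rarer than 1 in 35, so chance assignment of mice is made unlikely but not excluded. Mixed splits also hold the group difference as spread within their groups, which lowers their counts. A difference in sampling time that went with group would pass the same test. The split with 19 set HFD control 1, 3 and 4 with NM-FGF19 4 against the rest.

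Cholesterol synthesis genes were higher in NM-FGF19 than in HFD control livers, with a median log2 change of 2.11. A single library does not explain it, since the lowest median over the 8 fits without 1 library was 1.85, although the number of called genes ran from 1 to 21 in them. These fits do not show whether every treated mouse had the rise. NM-FGF19 3 was low, with Msmo1 at 32.7 CPM against 203 to 257 in the other NM-FGF19 libraries. With the clock score as a covariate the median was 2.09, which argues against clock phase only as far as the score tracks it. The score is built from Dbp, Per3, Arntl and Npas2. Clock phase that it does not track, as for Nr1d1 described below, stays open. A higher share of hepatocyte RNA would raise hepatocyte markers alike, and their median was 0.26, with 0 of 11 reaching the cholesterol median and the highest at 1.18. An effect of the FGF19 mRNA, or of the control mRNA it was compared with, remains open as a hypothesis, and no route was tested.

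Clock genes spread widely within groups. A candidate explanation is mice sampled at different times of day, and 7 of 8 clock genes deviated from their group means with the sign this predicts. The signs show that clock genes shifted together, and cannot tell sampling time from another shift of the clock in a mouse. Library scaling is argued against, because the ratio of Dbp to Arntl, which no scaling moves, spread at least 30.7 times as widely as the scaling factors in each group. For NM-FGF19 against HFD control, edgeR called 0 of 8 core clock genes. The clock scores overlapped (1.67 to 6.58 against 1.45 to 6.88), and 63 of 66 calls were shared with the covariate. These values argue against a time of day that differed between the groups as far as the score tracks it. Among the core genes Nr1d1 alone, named after its values were seen, did not overlap, at 119 to 172 against 76.1 to 108 CPM. Its deviations correlated at only 0.101 with Dbp minus Arntl, so the score hardly tracks it. A group difference of that kind stays open. Of all 19 clock genes 1 was higher at an unadjusted p under 0.05, and DESeq2 and voom called 0. That test is weak where mice of one group differ so much. Lean 3 and 4 had clock scores of −2.85 and −2.05, below every high-fat-fed mouse. Part of the diet comparison may therefore reflect sampling time or another shift of the clock, and this stays open.

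Acute phase genes were lower in HFD control than in lean livers, with a median of −1.60. A single lean animal with an acute phase response is not enough, since the median was −1.36 without lean 3. A lower share of hepatocyte RNA is argued against only weakly. Hepatocyte markers had a median of −0.57, short of the bound of −0.80 below which they would explain at least 50% of the change. The median SE of a single marker was 0.21, and no SE of the list's median was computed. With lean 3 and HFD control 3 both left out the acute phase median was −1.05 and the hepatocyte median −0.47, and with the clock score as a covariate they were −1.07 and −0.52. They were −1.25 and −0.26 with library totals alone. The first 2 of these hepatocyte values are close to 50% of the change, so a lower hepatocyte share stays open as part of the cause. A part tied to those animals, to sampling time or to another shift of the clock may remain too, next to diet itself.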

How the results depend on the processing

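The fits without the 2 libraries farthest from their groups (lean 3 and HFD control 3), with sample quality weights and with the clock score were chosen only after the result was seen; the others were set beforehand. All counts are of genes with an adjusted p under 0.05. Where the construction does not show it, the cause was not tested.

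For HFD control against lean, 770 genes rose and 502 fell. DESeq2 called 1299 and 921, library totals alone 2383 and 228, the fit without the 2 libraries 323 and 157, and the clock score 283 and 178. Genes that fell numbered 274 with only the 2 groups in the fit and 973 with quality weights. Leaving out 1 library gave 331 (without HFD control 3) to 926 (without HFD control 2) higher and 196 (without HFD control 1) to 602 (without HFD control 2) lower. For NM-FGF19 against HFD control, 43 rose and 23 fell. DESeq2 called 175 and 114, only the 2 groups 23 and 15, the fit without the 2 libraries 24 and 14, and quality weights 134 and 89. With library totals alone 26 were higher, and with the clock score 37 were lower. Leaving out 1 library gave 9 (without HFD control 1) to 62 (without NM-FGF19 3) higher and 8 (without NM-FGF19 1) to 34 (without HFD control 2) lower. For NM-FGF19 against lean, 154 rose and 74 fell. DESeq2 called 601 and 368, voom 65 and 47, only the 2 groups 74 and 43, and the clock score 69 and 40. With library totals alone 346 were higher, and with quality weights 164 were lower. Leaving out 1 library gave 43 (without NM-FGF19 4) to 130 (without NM-FGF19 3) higher and 24 (without NM-FGF19 1) to 71 (without lean 1) lower. Fits on fewer samples have less to estimate the spread from.

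Genes raised by diet and lowered by treatment numbered 13, and those lowered by diet and raised by treatment 30. They were 69 and 125 with DESeq2, 23 and 18 with library totals alone, 4 and 16 without the 2 libraries, and 59 and 89 with quality weights. Leaving out 1 library gave 1 (without NM-FGF19 1) to 25 (without HFD control 2) and 4 (without HFD control 1) to 50 (without NM-FGF19 3). The correlation of −0.55 became −0.46 with no filter on low counts, −0.49 without the 2 libraries and −0.62 with quality weights, and ran from −0.66 (without HFD control 2) to −0.48 (without HFD control 3) when 1 library was left out. The gene list tests passed for 18, 15 and 16 lists, and for 0, 0 and 0 with an estimated correlation. When 1 library was left out, 3, 3 and 4 of these lists lost their call in some fit, and with library totals alone 2, 0 and 1 did.

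The replicate numbers are shared between groups, so a fit with the number as a block was made. It called 384 and 209 genes for diet, 12 and 6 for NM-FGF19 against HFD control, and 25 and 15 against lean, with 1 diet-raised gene lower and 6 diet-lowered genes higher under treatment. No gene list lost its call, and against lean 17 lists passed in place of 16. Deviations of same-number pairs correlated at −0.363 to 0.0712 over 12 pairs, with a mean of −0.0780 against 0.0270 for other pairs, and 0 of 12 samples correlated best with their own number, so the numbers do not pair the mice.

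Of the named genes called, 66, 18 and 31 in the order above, 23, 6 and 11 kept their call in every alternative fitted, and none changed sign in any. Of 1312, 359 and 618 alternative values of these genes, 339, 109 and 139 missed the threshold, and 12 further fits gave no value for a named gene because it was not tested in them. Tnfsf4 and Fgf15 were too low to be tested at this depth.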

Other observations

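The Tnfsf4 test in this part was set out before its result was seen; the genes named here were chosen only after it, except Cyp8b1, Afp, Tsku, Csad, Nat8f5, Wnk4, Tnfsf4, Fgf15 and the examples of lists.

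Some genes in NM-FGF19 livers differed from both other groups in the same direction. Of these, 8 were higher and 9 lower, and all 8 and 8 of the 9 were not called between the diets. Akr1c18, for a steroid-reducing enzyme, rose by 6.24 ± 0.84 against HFD control (adjusted p = 0.00745) and by 4.71 ± 0.77 against lean (adjusted p = 0.0142). Mep1b, for a brush border protease, rose by 2.87 ± 0.53 and 2.39 (adjusted p = 0.0312 and 0.0433), and Tmem229a by 2.02 against each (adjusted p = 0.00699 and 0.00491). The other 5 were Afp, Wnk4, Fars2, Alcam and Ces2g. The 9 lower genes were Tsku, Csad, Nat8f5, Cyp8b1, Ces1b, Ces1g, Dop1b, Slc35e3 and Gde1. Ces1b stood at −1.84 and −1.57 and Ces1g at −1.72 and −1.31, and both belong to a family of near-identical copies. Gramd1b, for a cholesterol transporter, was the 1 gene called in both with opposite signs, at −1.08 against HFD control and 0.94 against lean. Both comparisons use the NM-FGF19 libraries. Independent lists would share 0.434 higher and 0.111 lower genes, and with the NM-FGF19 libraries split between the comparisons 0 to 1 and 0 to 4 genes were shared in 6 splits.

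Other lists passed the list test with diet at the preset correlation only. Unfolded protein and integrated stress response genes had a median of −0.53, and −0.22 with library totals alone (adjusted p = 0.00503, or 0.436 with an estimated correlation). Of 22, 3 fell and 1 rose, 0 to 7 fell with 1 library left out, and with library totals alone 2 were higher and 1 lower. Asns was at −3.06 (adjusted p = 0.0278) and Xbp1 at −1.14 (adjusted p = 0.035), and Psat1 rose by 1.80 (adjusted p = 0.0406). Male-biased liver genes had a median of −0.89 (adjusted p = 0.000179, or 0.404 with an estimated correlation), and −1.61 to −0.65 with 1 library left out. Of 15, 2 fell and 13 did not pass, and 0 to 6 fell with 1 library left out. Stellate cell markers had a median of 0.73 (adjusted p = 9.38e-05, or 0.369 with an estimated correlation). Of 11, 9 did not pass and 2 rose, Lrat by 1.21 (adjusted p = 0.0459) and Des by 1.01 (adjusted p = 0.0493). With library totals alone 8 rose, and without lean 3 and HFD control 3, 0 did. Erythroid markers were at 1.29, and 0.71 to 1.52 with 1 library left out (adjusted p = 0.0152, or 0.436 with an estimated correlation), with the test missing the threshold without HFD control 4 (0.0631) and with library totals alone (0.0664), and at −0.97 between NM-FGF19 and HFD control, −1.39 to −0.54 with 1 library left out (adjusted p = 9.36e-05, or 0.311 with an estimated correlation). In the latter 0 genes were called by edgeR or voom and 1 lower by DESeq2, and 4 lower at an unadjusted p under 0.05. Of these single genes Asns, Xbp1, Psat1, Lrat and Des kept their calls in 3, 3, 2, 0 and 2 of the 8 fits without 1 lean or HFD control library, with adjusted p up to 0.0791, 0.102, 0.122, 0.119 and 0.115, and Asns was at −3.92 without HFD control 2.

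Reads of an injected control mRNA could be counted on a mouse gene. The HFD control columns are named after mouse OX40L, encoded by Tnfsf4. The 4 HFD control libraries held 0 Tnfsf4 counts, which with a floor of 3 counts allows up to 0.0229 CPM over the group, so reads from a control mRNA for mouse OX40L counted on Tnfsf4 are argued against at this depth. The prediction named a fold change, which could not be computed because the gene was too low to be tested, so counts were used. Lean livers also held 0, and the NM-FGF19 libraries held 2, both in NM-FGF19 4. An mRNA of changed codons or one gone within 24 hours would leave no such reads and was not tested. Fgf15, the mouse counterpart of FGF19, had 2 counts, both in NM-FGF19 2, and 0 in the other 11 libraries.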
